A study of Mus musculus with 2 samples.

How the data were processed

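Gene expression was measured by droplet single-cell RNA sequencing (10x 3' v3) in YFP-positive liver cells of the Rb family triple knockout mouse. YFP marks cells in which Cre has acted on the floxed alleles, per the labels' protocols. There were 2 libraries, 1 of early lesions (a pool of 3 mice, with no map from cells to mice) and 1 of macroscopic lesions (the labels give no number of mice). Cells were obtained by enzymatic digestion and flow cytometry, per the labels' protocols.

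The deposited values are raw UMI counts per gene and cell barcode, written by Cell Ranger 3.0.2 per the file headers. A UMI count is the number of distinct RNA molecules captured. The submitters' processing notes name Cell Ranger 3.0.2, the mm10 build and Seurat 2.3.0, whose role they do not give. The gene annotation used for counting is not given in the sources used here. Each library lists 31053 genes by Ensembl identifier and symbol. Gene positions were taken from GENCODE M21 (GRCm38, the assembly behind mm10), matched by Ensembl identifier. The libraries are 3'-end counts, so a deletion upstream of the 3' end need not lower a gene's count. The authors' filtering of barcodes is not given in the sources used here. No YFP transcript is among the listed features, so the sort could not be checked on the counts.

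Barcodes were kept with at least 1000 UMIs, at least 300 genes and at most 25% mitochondrial UMIs. In the early library 656 of 3221 barcodes failed the UMI or gene minimum and 198 failed the mitochondrial limit. In the macroscopic library the numbers were 24 and 28 of 256. Scrublet, run per library as implemented in Scanpy, called 2 and 4 doublets, which were removed. That is 6 of 2673 barcodes (0.224%). Doublets of similar cells are not recognised this way, and barcodes of very high depth are not excluded as doublets. This left 2459 and 208 cells, with medians of 3047 and 15714 UMIs per cell and totals of 11853402 and 6881305 UMIs. In these sums 1 UMI corresponds to 0.0844 and 0.145 CPM. Counts were scaled to 10000 per cell and log-transformed for clustering only (2000 highly variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, seed 0).

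Clustering gave 14 clusters, which were named from marker lists of 16 cell classes fixed before the data were examined. A name needed at least 3 markers of the class at least 2-fold higher in the cluster than in the other cells, with 10 CPM added. The class with the highest share of such markers was taken. A cluster stayed unnamed where another class had more markers than the closest class among its top 10 genes by fold (at least 50 CPM and 10% of cells). It also stayed unnamed where genes of 7 hepatocyte function lists outnumbered its own markers there, or where its median UMIs were under those of its library divided by 3 with no own marker there. The scoring by share of markers and the hepatocyte-function rule were set after the clusters had been seen. They moved cells between classes. The scoring made cluster 9 B cell-like and left cluster 10 unnamed. The hepatocyte-function rule left cluster 2 unnamed (187 early cells, 7.60% of that library), which otherwise was closest to macrophages. The 4 unnamed clusters (2, 6, 10 and 11) held 592 early cells (24.1%) and 53 macroscopic cells (25.5%).

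UMIs of the hepatocyte-like cells were summed per library and expressed as CPM (a gene's UMIs relative to all UMIs of the sum, on the usual CPM scale). With 1 library per stage no test between stages was possible, and no p-value was computed. CPM values carry exact Poisson 95% intervals, CPM ratios the exact conditional binomial 95% interval, and shares of cells the exact Clopper-Pearson 95% interval. Where a count was 0, the limit given is 3 counts of the total, which is somewhat tighter than the upper end of the two-sided exact interval. All of these cover counting error only, not the spread between animals or preparations. A gene was measured if it had at least 10 CPM in 1 library and at least 20 UMIs in both together. Where a library had 0 UMIs, the fold was computed against a floor of 3 counts over the sum (3.30 CPM early, 0.540 CPM macroscopic) and is a lower bound. No fold is given where both sums were at or under 3 UMIs.

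There were 51 gene lists, 36 of gene groups and 15 of class markers, fixed before the data were examined. The leading genes of clusters 7 and 13, the hepatocyte-like clusters, define these clusters, so their levels are given and their ratios are not interpreted. Medians of lists that hold such a gene are also given without it, a step added after the data had been seen. Of the listed symbols, 2 were not among the features. For each list the median log2 CPM ratio (macroscopic over early) of its measured members is given with an order-statistic 95% interval, or the range where fewer than 6 members were measured. It is also placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries only. The median log2 ratio of all measured genes was not 0, so list medians are also given relative to it.

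Named genes followed a rule fixed before the data were examined. It takes the 12 highest and 12 lowest ratios among genes with at least 100 CPM and at least 100 UMIs in the library where they were higher, leaving out mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, Gm and Rik gene models, Xist and Y-linked genes. It also leaves out genes whose CPM in the other kept cells of that library was over 3 times that in its hepatocyte-like cells. Examples of a list come from its 3 most abundant measured members and the member with the largest absolute ratio. Which of these examples are shown was chosen after their values had been seen. Of the 12 highest ratios 11 are given. Finally, 12 genes tied to the Rb family, proliferation, liver identity and Notch are always given.

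Cells with at least 3 UMIs of the G1/S or the G2/M list were counted after thinning every cell to 2000 UMIs and leaving out shallower cells. Because thinning is random, 100 further draws were made after the first shares had been seen. Other choices were made after seeing the data. Barcodes with under 0.05% of UMIs from Malat1, a nuclear RNA, were split off. Clusters other than hepatocyte-like ones with at least 15 cells in each library were compared between libraries as shared clusters. Gene ratios were also taken relative to the median ratio of the same gene in these clusters. They hold other cell types, so such a value also moves with the ratio of the gene in those cells.

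Alternatives fixed before the data were examined were other limits on mitochondrial share, UMIs and genes, kept doublets, Leiden resolution 1.0, all kept cells, equal weight per cell, CPM without mitochondrial and ribosomal protein genes and the top 20 genes, median-of-ratios scaling, thinned cells and other filters on low values. The ratio and list steps were tested on simulated counts made from the real profiles, with barcodes of at least 1% Alb UMIs standing in for hepatocyte-like cells. Both simulated libraries were drawn from the pooled profile with counting error only, as the interval assumes. The simulation thus checks the calculation and not the spread between cells or preparations. Over 8388 simulated genes, 200 of them changed, the 95% interval of the ratio held the true value for 96.1% of genes. Of 200 unchanged random lists, 3.00% fell outside the central 95%. For 4-fold and 2-fold increases and decreases, the direction was right in 100% of the genes of each changed group, with median log2 ratios of 1.95, 0.90, -1.11 and -2.07 against true values of 1.92, 0.92, -1.08 and -2.08. Analyses used Python 3.11.15, Scanpy 1.11.5, AnnData 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9 and Matplotlib 3.10.9.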

Results

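Single-cell RNA was measured in YFP-positive cells sorted from livers of Rb family (Rb1, Rbl1 and Rbl2) triple knockout mice with floxed alleles, a model of hepatocellular carcinoma. The proteins of this family restrain E2F transcription factors and entry into S phase. Early lesions, pooled from 3 mice, gave 1 library of 3221 barcodes and 12637053 UMIs, and macroscopic lesions gave 1 library of 256 barcodes and 7271368 UMIs. The kept cells numbered 2459 and 208, with medians of 3047 and 15714 UMIs per cell. Each stage has 1 library, so no difference between them has a replicate check, and every interval covers counting error only.

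The genes targeted in the model had few UMIs in the hepatocyte-like cells of both libraries. In hepatocyte-like cells Rb1 (ENSMUSG00000022105, chromosome 14, 73183673 to 73325822, minus strand) had 20 UMIs in the early library, or 22.0 CPM (13.4 to 34.0), and 28 UMIs in the macroscopic library, or 5.04 CPM (3.35 to 7.29). Rbl1 (ENSMUSG00000027641, chromosome 2, 157145893 to 157204534, minus strand) had 0 and 2 UMIs, where a count of 0 allows up to 3.30 CPM. Rbl2 (ENSMUSG00000031666, chromosome 8, 91070057 to 91123844, plus strand) had 8.79 CPM (3.797 to 17.3) and 4.14 CPM (2.63 to 6.22). Over all kept cells Rb1 had 27.2 and 11.5 CPM, Rbl1 0.338 and 0.291 CPM, and Rbl2 25.5 and 9.16 CPM. The kept cells that were not hepatocyte-like had 27.6 (early) and 38.4 CPM (macroscopic) of Rb1, and 26.9 and 30.1 CPM of Rbl2. A 3' tag outside the deleted part checks nothing, no undeleted library was analysed here, and Rb1 overlaps the gene model Gm17233 on its strand.

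The animals differed in sex between the stages. Xist, the RNA that silences an X chromosome in female cells, had 9925 UMIs in the early library and 0 in the macroscopic one. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs each in the early library and 262, 356, 33 and 72 in the macroscopic one. In hepatocyte-like cells Xist stood at 1595 CPM (1514 to 1679) in the early library, and Ddx3y and Eif2s3y at 28.6 and 49.7 CPM in the macroscopic library. The list of these genes had 3 measured members and a median log2 ratio of 3.12 (range -11.53 to 3.91), which was -0.07 relative to the same genes in the clusters shared by both libraries (4, 6 and 10). Lesion stage and sex therefore cannot be separated in any comparison of these libraries.

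The first comparison asked which cell classes the sorted cells held at each stage. Hepatocyte-like cells were 1.87% of the early library (46 cells, 1.37 to 2.49) and 59.6% of the macroscopic library (124 cells, 52.6 to 66.3). Of these 124 barcodes 83 had almost no Malat1, a nuclear RNA, and whether they are whole cells was not settled. Without such barcodes the macroscopic library held 41 hepatocyte-like and 77 other cells, and the early library 46 and 2348. Macrophage-like cells were 63.5% of the early library (1562 cells, 61.6 to 65.4) and 0.962% of the macroscopic library (2 cells, 0.117 to 3.43). This class leaves out unnamed clusters closest to macrophages (2 and 11) or monocytes (6), and cluster 6 held 11.1% of the macroscopic cells. The low macroscopic share therefore does not show that such cells were nearly absent. Cholangiocyte-like cells, resembling the lining of bile ducts, were 4.72% of the early library (116 cells, 3.91 to 5.63). They were 0 of 208 cells in the macroscopic library, which allows a share of up to 1.44%, and 1 cell there under 5 of the 6 other filter and clustering settings. T cell-like cells were 3.05% (75 cells, 2.41 to 3.81) and 8.65% (18 cells, 5.21 to 13.3).

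Neutrophil-like cells were 1.59% (39 cells, 1.13 to 2.16) of the early and 1.92% (4 cells, 0.526 to 4.85) of the macroscopic library. B cell-like cells were 0.773% (19 cells, 0.466 to 1.20) and 1.92% (4 cells, 0.526 to 4.85), and plasmacytoid-like cells 0.407% (10 cells, 0.195 to 0.747) and 1.44% (3 cells, 0.298 to 4.16). For these 3 classes the intervals of the libraries overlapped. Unnamed clusters held 24.1% (22.4 to 25.8) and 25.5% (19.7 to 32.0). They were led by Rgn, Pck1 and Hpd in cluster 2 (187 and 0 cells), Gpnmb, H2-M2 and Mmp12 in cluster 6 (345 and 23 cells), Fabp4, Plvap and Col3a1 in cluster 10 (22 and 30 cells) and Saa3 and Retnla in cluster 11 (38 and 0 cells). By raised markers clusters 2 and 11 were closest to macrophages, cluster 6 to monocytes and cluster 10 to endothelial cells. The YFP sort, the minimum of 1000 UMIs and the higher depth of the macroscopic library can each set these shares. So can the counting of barcodes with almost no Malat1 as cells. With at least 2000 UMIs and 500 genes per cell the neutrophil-like class was lost in both libraries (0%), and the B cell-like and plasmacytoid-like classes were lost under other settings (0%).

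**Figure D1:**
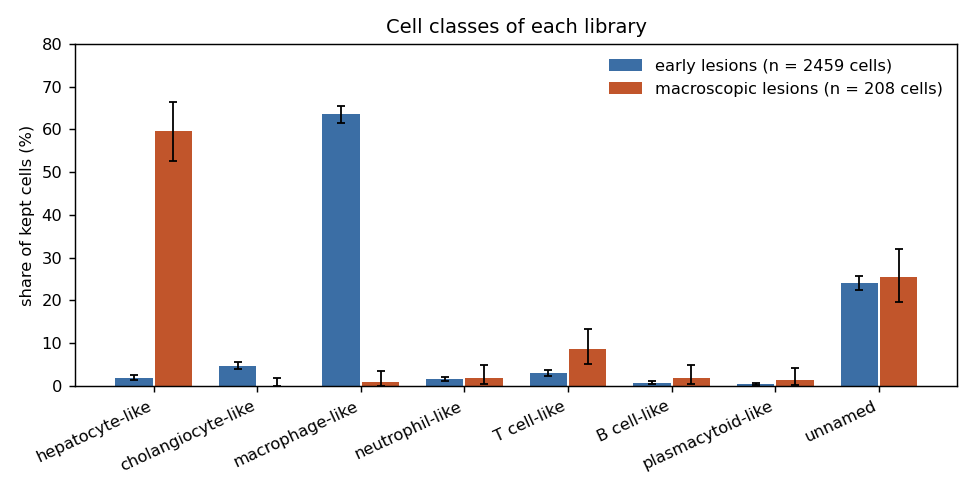
Share of kept cells (%) in each named class and in unnamed clusters, for the early library (2459 cells) and the macroscopic library (208 cells), with exact 95% intervals of counting error. Hepatocyte-like cells were 1.87% and 59.6%, and macrophage-like cells 63.5% and 0.962%. The unnamed clusters include some closest to macrophages or monocytes. Of the 124 macroscopic hepatocyte-like barcodes 83 had almost no Malat1.

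The second comparison asked how hepatocyte-like cells of macroscopic lesions differed from those of early lesions. Immediate-early and heat-shock genes were far higher in the macroscopic library, with a median log2 ratio of 2.96 over 25 genes. Measured bile-duct and progenitor genes were also higher, at 0.84 over 13 genes, while the bile-duct keratins Krt19 and Krt7 had 0 UMIs in both sums. Genes of specialised hepatocyte metabolism were lower, with medians near -1.1 for the urea cycle, cytochrome P450 and bile acid lists. E2F targets of the G1/S transition had a median of -0.47 over 54 genes (-0.24 relative to all measured genes). A list of mitotic genes stood at -0.55 over 59 genes (-0.32 relative), at 0.022 in cells thinned to equal depth (-0.13 relative) and at -0.07 with equal weight per cell (0.46 relative).

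The early sum held 46 cells and 909625 UMIs (median 18193 per cell), all in cluster 7. The macroscopic sum held 124 cells and 5551843 UMIs (median 19965.5), all in cluster 13. Of these UMIs 3763905 came from the 41 barcodes with Malat1 and 1787938 from the 83 with almost none. The ratios are therefore weighted to the 41 deep barcodes, among which multiplets are not excluded. Thinned cells and equal weight per cell count each barcode alike, so the 83 weigh more there. A cluster of 1 library may be that library rather than a cell type. Of 8717 measured genes, 876 were at least 2-fold higher and 1589 at least 2-fold lower in the macroscopic library. The median log2 ratio of all measured genes was -0.23. With median-of-ratios scaling the split was 1262 and 1031 genes, and in macroscopic barcodes with at least 0.05% of UMIs from Malat1 it was 1087 and 1111.

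Nuclear and mitochondrial RNA separated the macroscopic hepatocyte-like barcodes. Malat1, a long RNA kept in the nucleus, made up under 0.05% of UMIs in 83 of 124 of them (66.9%; 57.9 to 75.1). In the early library this held for 0 of 46, which allows up to 6.52%. The 83 barcodes had a median of 0.0592% mitochondrial UMIs, against 7.59% in the other 41 and 8.06% in early hepatocyte-like cells. They also had fewer UMIs, with a median of 14787 against 115264, and 2904 against 8779 genes. Among the other kept cells of the macroscopic library, 7 of 84 lay below the limit (8.33%; 3.42 to 16.4). Of the 124 barcodes, 5 lay between 0.02% and 0.1%.

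**Figure D2:**
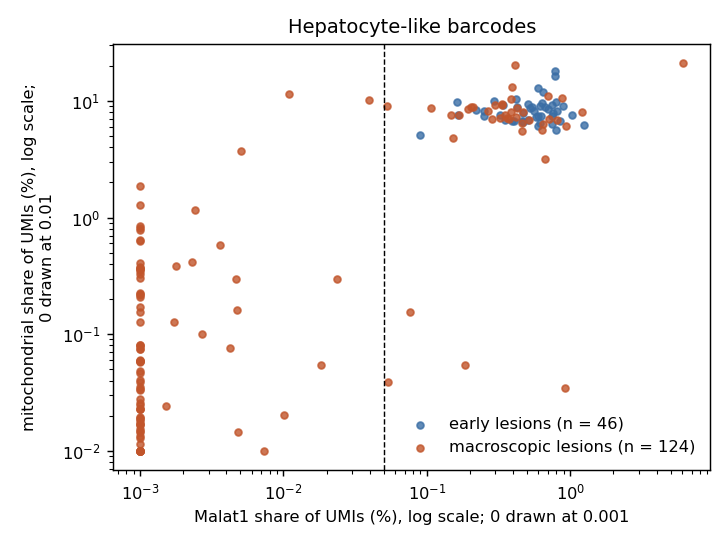
Malat1 share of UMIs (%, log axis) against mitochondrial share of UMIs (%, log axis) for each hepatocyte-like barcode of the early (46) and macroscopic (124) library, with a dashed line at 0.05% Malat1. The 83 macroscopic barcodes left of the line had a median mitochondrial share of 0.0592%, and no early barcode lay there.

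Among the 12 highest ratios was that of Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039, minus strand), a stress-induced transcription factor. It was 44.5-fold higher in the macroscopic library (25.4 to 86.2), at 587 against 13.2 CPM, a log2 ratio of 5.47 against a median of 2.305 in the shared clusters. The chaperone Hsph1 was 30.3-fold higher (12.9 to 93.5) and the small heat-shock protein Hspb1 17.3-fold (13.5 to 22.5). Saa1, an acute-phase apolipoprotein (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980, minus strand), was 61.5-fold higher on 2 early UMIs (17.0 to 509). Ccl20, a chemokine (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167, plus strand), had 712 UMIs against 0 and was at least 38.9-fold higher.

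Nme2, a nucleoside diphosphate kinase (ENSMUSG00000020857, chromosome 11, 93949814 to 93956259, minus strand), was 115-fold higher (45.0 to 424). Its count is uncertain because it overlaps Gm20390 on the same strand. Usp50 was 29.4-fold higher (14.3 to 73.4). The histone genes Hist1h2ap and Hist1h2ae were 22.1-fold (15.1 to 33.9) and 16.9-fold (8.55 to 39.3) higher, and near-identical copies in their family can share reads. In barcodes with Malat1 their log2 ratios of 4.47 and 4.08 were 3.46 and 1.92. Nme2, Hsph1, Usp50, Hist1h2ap and Hist1h2ae were at least 2-fold higher in each of the 3 shared clusters too, and relative to these clusters Hist1h2ap turned to a log2 ratio of -1.44. Tff3 and Spp2 are also among the 12, but they are leading genes of cluster 13, so only their levels are given, 6.60 and 544 CPM for Tff3 and 0 and 168 CPM for Spp2.

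The 12 lowest ratios included that of Cyp2b9, a cytochrome P450 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661, plus strand). It was 342-fold lower in the macroscopic library on 2 UMIs there (92.4 to 2857). Angptl4, an inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830, minus strand), was 26.0-fold lower (18.8 to 36.7). Pck1, the rate-controlling enzyme of gluconeogenesis (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273, plus strand), was 15.3-fold lower (12.1 to 19.5), at 17.8 against 273 CPM. Kyat3, a kynurenine aminotransferase, was 14.9-fold lower (11.5 to 19.5), the glutathione transferase Gstm2 11.6-fold (8.47 to 16.1) and the sulfotransferase Sult1a1 8.67-fold (7.84 to 9.59). The other 6 are leading genes of cluster 7, so only their early and macroscopic levels are given. These were 4290 and 5.94 CPM for Ptgds, a prostaglandin D synthase, 2491 and 47.2 CPM for Hamp, the iron hormone hepcidin, and 2136 and 145 CPM for Mup20, a urinary protein. Cyp3a11 had 1275 and 93.5 CPM, Cyp2a4 726 and 62.7 CPM, and Cyp2a12 375 and 36.02 CPM. Cyp2b9, Cyp2a4, Cyp3a11, Gstm2 and Mup20 belong to families whose members can share reads.

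**Figure D3:**
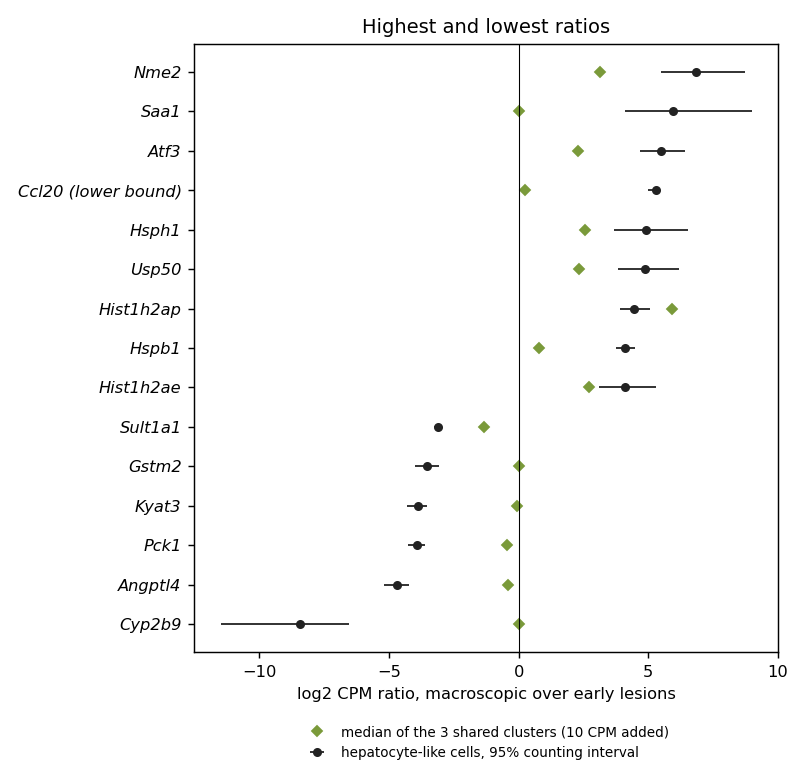
Log2 CPM ratio (macroscopic over early) in hepatocyte-like cells for 9 of the 12 highest and 6 of the 12 lowest genes, with exact 95% counting intervals, and the median ratio of the same genes over the 3 shared clusters with 10 CPM added. Nme2, Hsph1, Usp50, Hist1h2ap and Hist1h2ae were also at least 2-fold higher in each shared cluster. The leading genes of clusters 7 and 13 are not drawn.

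Among metabolic lists, urea cycle and amino acid breakdown had a median log2 ratio of -1.12 (-1.54 to -0.50; -0.89 relative to all measured genes). Of 28 measured members 15 were at least 2-fold lower and 1 higher. Ass1, which makes argininosuccinate, was 2.40-fold lower (2.24 to 2.56). Bhmt and Cps1, leading genes of cluster 7, had 3529 and 1217 CPM there and 575 and 235 CPM in cluster 13. Cytochrome P450 and conjugation genes had a median of -1.10 (-1.62 to -0.73; -0.86 relative), with 15 of 29 lower and 2 higher. Gstm1, a glutathione transferase, was 4.003-fold lower (3.81 to 4.21), and Cyp2c29 (95 UMIs against 0) at least 193-fold lower. Bile acid synthesis and transport had a median of -1.15 (-2.23 to 0.07; -0.91 relative), with 8 of 15 lower and 1 higher. Slc10a1, the main bile acid importer, was 4.70-fold lower (3.90 to 5.64) and Akr1c6 3.19-fold lower (2.88 to 3.53). All 3 medians lay at or below the 0.01 percentile of matched random lists. Leading genes of clusters 7 and 13 were left out of the lists in a further step, chosen after the data had been seen. The urea cycle median was then -0.95 (-1.53 to -0.45) over 26 genes and the cytochrome P450 median -1.05 (-1.50 to -0.73) over 26.

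Periportal genes had a median of -1.12 (-2.27 to -0.41; -0.89 relative, percentile 0), with 13 of 21 lower and 1 higher. The lipid-droplet enzyme Hsd17b13 was 2.33-fold lower (2.21 to 2.45). Pericentral genes had a median of -1.15 (-3.77 to 1.25; -0.92 relative, percentile 0.03), with 7 of 12 lower and 3 higher; Mgst1 was 2.32-fold lower (2.19 to 2.45). Relative to the shared clusters, the pericentral median was 0.042, and Gstm1 and Mgst1 turned to log2 ratios of 0.13 and 0.19. Without leading genes the periportal median was unchanged at -1.12 over 19 genes, with 12 lower and 0 higher, and the pericentral median was -1.10 over 11. Gluconeogenesis had a median of -1.04 (-2.45 to -0.20; -0.80 relative, percentile 0.21), with 6 of 11 lower and 0 higher. In this list Fbp1, fructose bisphosphatase, was 2.45-fold lower (2.27 to 2.65).

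Fatty acid oxidation and ketogenesis had a median of -0.50 (-1.27 to -0.35; -0.27 relative, percentile 1.89), with 8 of 22 lower and 1 higher, and -0.26 with median-of-ratios scaling. The fatty acid binding protein Fabp1 was 1.54-fold higher (1.47 to 1.61), though relative to the shared clusters its log2 ratio was -0.64. Secreted liver proteins had a median of -0.60 (-0.83 to -0.10; -0.37 relative, percentile 0.04), with 4 of 26 lower and 3 higher. Their median was -0.93 relative to the shared clusters and -0.63 without leading genes. In this list Apoe, which carries lipids, was 1.49-fold lower (1.46 to 1.53) and Serpina3k, a protease inhibitor, 11.5-fold higher (7.17 to 19.9). Alb, the albumin gene, had 22627 CPM in the early and 28968 CPM in the macroscopic library, a ratio of 1.28 (1.26 to 1.30). Its log2 ratio of 0.36 turned to -0.13 in thinned cells, -0.19 with equal weight per cell and -0.86 relative to the shared clusters. The last value subtracts a log2 ratio of 1.21 in clusters of other cell types. The other kept cells held only 572 (early) and 197 CPM (macroscopic) of Alb, so it does not show a fall in hepatocyte-like cells. Fatty acid synthesis had a median of 0.10 (-0.60 to 1.61; 0.33 relative, percentile 80.8), and -0.67 in thinned cells and -0.57 with equal weight per cell. Of its 18 members 6 were higher and 1 lower, with the desaturases Scd1 and Scd2 4.09-fold (3.48 to 4.84) and 6.62-fold (4.55 to 10.0) higher.

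Medians of 3 lists of proliferation genes were below 0, with members in both directions. E2F targets of the G1/S transition had a median log2 ratio of -0.47 (-0.79 to -0.37; -0.24 relative, percentile 1.23), with 15 of 54 at least 2-fold lower and 0 at least 2-fold higher. Their median was -0.30 in thinned cells (-0.46 relative), -0.87 with equal weight per cell (-0.34 relative) and -0.23 with median-of-ratios scaling. Rrm2, a subunit of ribonucleotide reductase, was 3.09-fold lower (2.70 to 3.53), E2f7, a repressor of the E2F family, 5.32-fold (3.05 to 9.20) and the helicase subunit Mcm7 1.54-fold (1.32 to 1.79). G2/M genes had a median of -0.55 (-0.67 to -0.29; -0.32 relative, percentile 0.12), with 12 of 59 lower and 3 higher, but in thinned cells the median was 0.022. Thinning left 2332 measured genes, whose median was 0.16, so relative to them the list stood at -0.13. With equal weight per cell the median was -0.07, which is 0.46 relative to all measured genes, so the direction of this list relative to other genes depended on the weighting. Mki67, a marker of cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand), was 3.76-fold lower (3.29 to 4.29), at 105 against 396 CPM. It stood at 150 CPM in the macroscopic barcodes with Malat1 and 10.6 CPM in those without. Hmgb2, a chromatin protein, was 1.55-fold lower (1.42 to 1.68). Birc5, which acts in chromosome segregation, was 1.35-fold higher (1.18 to 1.54), with a log2 ratio of -1.37 relative to the shared clusters.

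The list of RB and E2F network genes had a median of -0.65 (-1.22 to -0.07; -0.41 relative, percentile 3.83), with 8 of 22 lower and 0 higher. Relative to the shared clusters the medians of the 3 lists were further below 0, at -1.17 for G1/S, -1.28 for G2/M and -1.24 for the RB and E2F network. By construction this subtracts the ratios in clusters of other cell types, where Mki67, for example, was higher in the macroscopic library (median log2 ratio 1.83). These values therefore show no further fall in hepatocyte-like cells. E2f1, a transcription factor that RB proteins bind, was 2.33-fold lower (1.72 to 3.13), at 29.7 against 69.3 CPM. The kinase Cdk4 was 2.29-fold lower (1.90 to 2.76) and the cell-cycle inhibitor Cdkn1c 7.97-fold (5.41 to 11.8). Cdkn1a, the inhibitor p21, had 312 and 372 CPM, a ratio of 1.19 (1.05 to 1.35) that turned to a log2 ratio of -1.24 relative to the shared clusters. Ccnd1 had 1 and 3 UMIs and gives no ratio.

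After thinning to 2000 UMIs, 93.5% of early hepatocyte-like cells (43 of 46; 82.1 to 98.6) and 85.5% of macroscopic ones (100 of 117; 77.8 to 91.3) had at least 3 UMIs of the G1/S list. For the G2/M list the shares were 78.3% (36 of 46; 63.6 to 89.1) and 92.3% (108 of 117; 85.9 to 96.4), with 0 early and 7 macroscopic cells left out as too shallow. Over 100 draws of the thinning the G2/M medians were 84.8% (71.7 to 91.3) and 88.9% (82.9 to 94.9), and the G1/S medians 95.7% (89.1 to 100) and 87.2% (79.5 to 92.3). Unthinned shares were 100% and 99.2% for G2/M, and 100% and 97.6% for G1/S. The G2/M shares ran against the list's summed level, 6282 CPM in the early and 4700 CPM in the macroscopic library, so no order is read from them. The shares show how many cells hold RNA of a list and do not measure cycling. For G1/S the summed levels were 5243 and 3649 CPM. In early macrophage-like cells (median 2463 UMIs) the thinned shares were 24.4% for G2/M and 19.7% for G1/S, in cholangiocyte-like cells (median 10814 UMIs) 45.2% and 53.9%, and in early T cell-like cells (median 2621 UMIs) 42.6% and 27.9%.

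Bile-duct and progenitor genes had a median log2 ratio of 0.84 (0.12 to 1.76; 1.08 relative, percentile 99.7), with 6 of 13 at least 2-fold higher and 1 lower in the macroscopic library. Epcam, an adhesion molecule of bile-duct and progenitor cells, was 14.8-fold higher on 5 early UMIs (6.30 to 45.8). The keratin Krt18 was 2.71-fold higher (2.49 to 2.97) and Spp1, osteopontin, 1.55-fold (1.46 to 1.65). The listed keratins Krt19 and Krt7 had 0 UMIs in both hepatocyte-like sums, against 374 and 284 CPM in early cholangiocyte-like cells. Cholangiocyte-like cells were 116 in the early library and 0 or 1 in the macroscopic library, depending on the setting, and over all kept cells this median was -1.26. The 7 measured cholangiocyte markers are all members of this list, so their median of 0.84 (-0.46 to 3.89, percentile 97.8) adds no separate evidence. Oncofetal and liver tumour genes had a median of 1.01 (-1.62 to 2.88; 1.24 relative, percentile 100), with members in both directions, 11 of 22 higher and 7 lower. Without leading genes that median was 0.68 over 20 genes, with 9 higher and 7 lower. Bex1 was 2.32-fold higher (1.93 to 2.81), while the imprinted RNA H19 was 3.08-fold lower (2.98 to 3.17), at 2175 against 6696 CPM, and Tspan8 265-fold lower on 2 macroscopic UMIs (71.3 to 2227). Afp, the fetal albumin, had 2 and 17 UMIs, a ratio of 1.39 (0.331 to 12.4) within counting error.

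The Notch pathway list had a median of -0.09 (-0.78 to 2.65; 0.15 relative, percentile 67.1), with 1 of 7 measured members at least 2-fold higher, and the median was 0.15 with median-of-ratios scaling and -0.99 with equal weight per cell. That member was Hes1, a Notch-induced repressor (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796, plus strand), 6.29-fold higher (4.58 to 8.88) at 270 against 42.9 CPM. Its log2 ratio of 2.65 was close to its median of 2.43 in the shared clusters. Notch1 had 22.2 and 23.1 CPM in the macroscopic and early library and Notch2 33.1 and 31.9 CPM, differences within counting error. The log2 ratio of Notch1 (-0.06) was 0.18 with median-of-ratios scaling, and that of Notch2 (0.06) was -0.43 with equal weight per cell and, outside its counting interval, -0.75 relative to the shared clusters. Notch3 had 0 UMIs in both. WNT targets had 3 measured members and a median of 1.25 (range -2.43 to 3.27; 1.48 relative, percentile 99.1), which was -1.39 with no filter and 1 UMI added.

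The dissociation stress list holds immediate-early and heat-shock genes that respond to tissue handling. Its median log2 ratio was 2.96 (1.72 to 3.28; 3.19 relative, percentile 100), with 19 of 25 at least 2-fold higher and 0 lower. Besides Atf3, Hsph1 and Hspb1, the immediate-early gene Ier2 was 3.29-fold higher (2.77 to 3.93). Jund, a subunit of the AP-1 transcription factor, was 1.72-fold higher (1.55 to 1.92), with a log2 ratio of -0.27 relative to the shared clusters. Relative to the shared clusters the median was 1.45. Targets of p53 had a median of 0.97 (-0.68 to 2.15; 1.20 relative, percentile 100), with 9 of 20 higher and 3 lower. Btg2, which is also a stress-list gene, was 9.71-fold higher (7.24 to 13.4) and the secreted factor Gdf15 3.44-fold (2.82 to 4.22). Genes of the unfolded protein response had a median of 0.61 (0.10 to 1.43; 0.85 relative, percentile 99.4), with 6 of 18 higher and 2 lower, and the chaperone Hspa5 was 2.81-fold higher (2.57 to 3.09), a log2 ratio of 1.49 against a median of 0.89 in the shared clusters. Calr, another chaperone, was 1.46-fold higher (1.34 to 1.59), but its log2 ratio was -0.55 in thinned cells and -0.17 with equal weight per cell.

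Interferon response genes had a median of 0.47 (-0.49 to 0.93; 0.70 relative, percentile 99.0), with 3 of 15 higher and 0 lower, and -0.23 among genes with at least 50 CPM and 100 UMIs. Bst2 was 2.18-fold higher (1.88 to 2.53) and Ifitm3 1.43-fold lower (1.35 to 1.52). MHC class I genes had a median of 0.41 (-0.32 to 1.31; 0.64 relative, percentile 93.6), with 3 of 14 higher and 0 lower, and B2m was 1.73-fold higher (1.61 to 1.86). Acute-phase genes went both ways, with a median of -0.69 (-1.45 to 0.94; -0.45 relative, percentile 0.425), 6 of 23 higher and 9 lower. Their median was -1.53 in thinned cells, and -0.37 over 20 genes without leading genes. Lcn2, an iron-binding acute-phase protein, was 2.72-fold higher (2.55 to 2.91), a log2 ratio of 1.44 against a median of 1.22 in the shared clusters. Haptoglobin, Hp, had 4355 and 4202 CPM and a log2 ratio of -0.05, which was 0.19 with median-of-ratios scaling and 0.019 without mitochondrial, ribosomal protein and top 20 genes.

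Complement and coagulation had a median of -0.21 (-0.57 to -0.04; 0.02 relative, percentile 15.5), 0.027 with median-of-ratios scaling and 0.14 in barcodes with Malat1, but -0.76 in thinned cells and -0.89 with equal weight per cell. Medians of other lists lay inside the central 95% of random lists. Liver transcription factors stood at -0.20 (0.04 relative), 0.043 with median-of-ratios scaling and -0.77 in thinned cells (-0.93 relative). NRF2 targets of the oxidative stress response stood at -0.21 (0.03 relative), 0.034 with that scaling, 0.24 relative to the shared clusters and -0.88 in thinned cells (-1.04 relative). Glycolysis stood at -0.29 (-0.05 relative; 0.012 relative to the shared clusters). Nuclear genes of oxidative phosphorylation stood at 0.04 (0.28 relative), but at -0.16 in barcodes with Malat1. Mitochondrially encoded genes stood at -0.40 (-0.17 relative), but at 0.12 in barcodes with Malat1 and 0.33 without the mitochondrial limit, and at -1.29 with equal weight per cell (-0.76 relative) and -1.26 in thinned cells (-1.42 relative). Epithelial-to-mesenchymal genes stood at 0.0089 (0.24 relative; -0.54 with equal weight per cell), and apoptosis and survival genes at -0.01 (0.22 relative; 0.23 with median-of-ratios scaling). Nucleotide and one-carbon synthesis stood at 0.16 (0.40 relative; -0.16 with equal weight per cell). The medians of ribosome biogenesis (0.25; 0.49 relative, percentile 99.2) and cholesterol synthesis (0.23; 0.47 relative, percentile 98.4) lay above that range, with 4 of 24 and 2 of 24 members at least 2-fold higher and 1 and 3 lower. The cholesterol median was -0.25 with equal weight per cell and 0.61 in thinned cells, and relative to the shared clusters the ribosome biogenesis median was -0.016.

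Liver genes with a known sex bias were compared because the sex of the animals differed. All 9 measured members of the female-biased list were at least 2-fold lower in the macroscopic library, with a median log2 ratio of -3.24 (-5.06 to -1.56; -3.00 relative, percentile 0). Without Cyp2a4, a leading gene of cluster 7, all 8 others were lower, with a median of -2.98 (-8.42 to -1.13). Besides Cyp2b9, the sulfotransferase Sult2a1 was 2.19-fold lower (1.86 to 2.57). The male-biased list had 7 measured members, 2 at least 2-fold higher and 3 lower, and a median of 0.41 (-3.88 to 2.42; 0.65 relative, percentile 81.6). Without leading genes it was unchanged at 0.41 over 5 genes, 1 higher and 2 lower. That median was -0.59 in thinned cells and -1.34 with equal weight per cell.

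Markers of other classes were checked in the hepatocyte-like sums. Dendritic markers had a median log2 ratio of 2.68 over 3 measured members (range 2.64 to 4.02, percentile 99.8), all of them MHC class II genes, which present peptides to helper T cells. H2-Ab1 was 6.42-fold higher in the macroscopic library (4.17 to 10.4) and H2-Aa 6.25-fold (3.13 to 14.6). Cd74, the invariant chain of MHC class II, was 25.1-fold higher (18.2 to 35.7), at 1023 against 40.7 CPM, while the other kept cells of the macroscopic and early library held 9013 and 9439 CPM. These 3 genes and the dendritic median turned negative over all kept cells, where the median was -2.18. Macrophage markers had a median of -1.56 over 3 measured members (range -6.93 to -0.38, percentile 1.89), of which 2 were at least 2-fold lower. Among them C1qa, a complement subunit, was 2.94-fold lower (1.39 to 5.89), with a log2 ratio of -1.56 that was -3.43 in barcodes with Malat1, and Cd5l 122-fold lower on 1 macroscopic UMI (19.5 to 5059). Relative to the shared clusters the macrophage median and C1qa were both at 1.32. Plasmacytoid and plasma-cell markers, with 4 measured members each, had medians of -0.79 (range -1.35 to 1.12, percentile 11.9) and 1.37 (range -0.13 to 3.62, percentile 97.0). Endothelial, neutrophil, fibroblast and erythroid lists had 1 measured member each, monocyte and B cell lists 2, and T cell, NK, mesothelial and platelet lists 0.

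**Figure D4:**
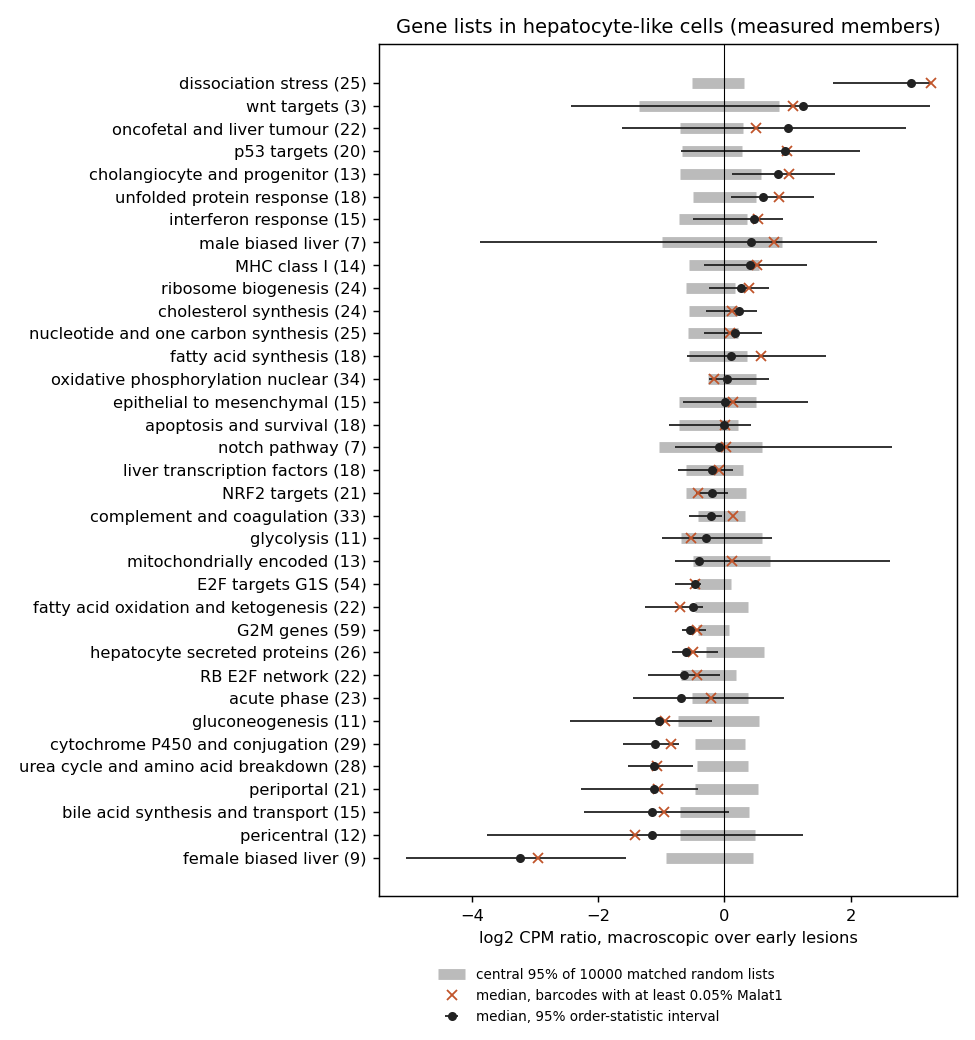
Median log2 CPM ratio (macroscopic over early) of each gene-group list with at least 3 measured members in hepatocyte-like cells (number measured in brackets), with its 95% order-statistic interval, the central 95% of 10000 matched random lists (grey) and the median in barcodes with at least 0.05% Malat1 (crosses). The class marker lists and the sex chromosome list are not drawn. Dissociation stress stood at 2.96 and the female-biased list at -3.24; the complement and coagulation median turned from -0.21 to 0.14 in barcodes with Malat1.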

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

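This check of barcodes over the mitochondrial limit was chosen after the data had been seen. The comparisons leave out barcodes with over 25% mitochondrial UMIs, 198 of 3221 in the early library (6.15%) and 28 of 256 in the macroscopic library (10.9%). Hepatocyte marker RNA was found in them above what a count of 0 allows. In the early library the markers made up 0.670% of their non-mitochondrial UMIs (994 UMIs), against 8.58% in hepatocyte-like cells and 0.259% in the other kept cells. In the macroscopic library they made up 11.2% (6594 UMIs), against 8.35% and 0.094%. The macroscopic barcodes over the limit had a median of 89.96% mitochondrial UMIs and 9798.5 UMIs, and the early ones 34.6% and 1183. Macrophage markers made up 2.82% of non-mitochondrial UMIs in the early barcodes and 0.0187% in the macroscopic ones. The limit lowered the number of macroscopic hepatocyte-like cells. Without it 145 of 231 macroscopic and 47 of 2562 early cells were hepatocyte-like, against 124 of 208 and 46 of 2459 with it. Both shares stayed within their reported counting intervals. Unnamed cells were 10.8% of the macroscopic and 19.3% of the early library without the limit.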

How the results depend on the processing

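Results restricted to the Malat1-containing barcodes, those relative to the shared clusters and list medians without the leading genes of clusters 7 and 13 were added after the data had been seen, and the other alternatives were fixed before. No paired analysis was possible because each group has 1 library. Unless a construction shows it, the cause of a change with the setting was not tested. Of 605 list medians under an alternative, 549 stayed within the interval of the reported value (37 with another sign) and 40 left it (6 with another sign). A further 16 changed sign where that interval excluded 0. Leiden resolution 1.0 gave the same 46 and 124 hepatocyte-like cells and the same 8717 measured genes, so its 41 medians add no check. Other limits on UMIs and genes and kept doublets also changed few of these cells (46 early, 118 to 130 macroscopic). These totals therefore overstate how stable the medians are. Ratios of the leading genes of clusters 7 and 13 are not listed. Of 921 log2 ratios of other named genes, 688 stayed within their counting interval (10 with another sign) and 197 left it (1 with another sign). A further 36 changed sign where the interval excluded 0. For the shares of classes the numbers were 70 within and 26 outside, for the shares of cells with G1/S or G2/M genes 20 and 28, for numbers of genes (within 1.5 times) 19 and 9, and for CPM values 5 and 5. With thinned cells some lists, among them the female-biased list, had too few measured genes for a median.

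Using all kept cells in place of hepatocyte-like cells changed the sign of 21 of 41 list medians and 24 of 65 gene ratios. By construction this mixes classes whose shares differ between the libraries, with hepatocyte-like cells at 1.87% and 59.6%. Medians whose interval excluded 0 changed sign to 2.43 for secreted proteins, 1.38 for periportal genes, 1.30 for urea cycle and amino acid breakdown, 1.72 for cytochrome P450 and conjugation, 0.95 for fatty acid oxidation and 0.97 for gluconeogenesis. They also became -1.26 for bile-duct and progenitor genes, 1.43 for G1/S targets, 1.53 for G2/M genes, 0.016 for the RB and E2F network, 2.42 for complement and coagulation and -2.18 for dendritic markers. Medians that left their interval, of which liver transcription factors, bile acid genes, acute-phase genes and cholangiocyte markers changed sign, became 1.29 for liver transcription factors, 1.42 for bile acid genes, 1.10 for cholesterol synthesis, -1.11 for glycolysis, 0.84 for oxidative phosphorylation, 0.76 for nucleotide synthesis and 1.97 for acute-phase genes. They also became -0.89 for NRF2 targets, 0.75 for dissociation stress, -1.05 for apoptosis and survival, 6.30 for sex chromosome genes, -0.58 for female-biased genes and -1.26 for cholangiocyte markers. Gene ratios (log2) whose interval excluded 0 changed sign to 0.67 for Mki67, 2.11 for Hsd17b13, 0.33 for Gstm1, 0.53 for Mgst1, 1.38 for Ass1, 0.95 for Akr1c6 and 1.12 for Slc10a1. They also became 1.37 for Fbp1, 1.35 for Rrm2, 1.41 for Mcm7, 0.91 for Hmgb2, 0.45 for Cdkn1c, -1.26 for Spp1 and -1.48 for Epcam. The rest became 1.77 for H19, 3.11 for Hp, -0.42 for B2m, 1.92 for Sult2a1, -1.76 for Cd74, -1.98 for H2-Ab1 and -2.37 for H2-Aa. Genes at least 2-fold higher and lower numbered 1935 and 2413. The shares of cells with G2/M genes were 25.3% (early) and 73.5% (macroscopic), and those with G1/S genes 20.1% and 62.8%. Levels became 11.5 CPM for Rb1 (macroscopic), 25.5 and 9.16 CPM for Rbl2, 837 CPM for Xist and 38.1 CPM for Ddx3y.

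Thinning and equal weight per cell change the mix of barcodes as well as the depth. By construction the 83 of 124 macroscopic barcodes with almost no Malat1 then weigh more than in the sum, where they held 1787938 of 5551843 UMIs. Effects of depth and of this mix were not separated. In cells thinned to 2000 UMIs the G2/M median changed sign to 0.022. The median of all measured genes was 0.16 there, over 2332 genes, so relative to it the G2/M median was -0.13. Other medians became -0.77 for liver transcription factors, -0.67 for fatty acid synthesis, 0.61 for cholesterol synthesis, -1.26 for mitochondrially encoded genes, -0.30 for G1/S targets, -1.53 for acute-phase genes, -0.76 for complement and coagulation and -0.88 for NRF2 targets. The log2 ratios of Alb and Calr became -0.13 and -0.55, and 550 genes were higher and 398 lower by 2-fold. With equal weight per cell (mean over cells of the CPM per cell) the median of all measured genes was -0.53 and list medians became -1.29 for mitochondrially encoded genes, -0.99 for the Notch pathway, -0.87 for G1/S targets, -0.072 for G2/M genes, -0.89 for complement and coagulation and 2.49 for dendritic markers. Relative to all measured genes the G2/M median was 0.46 there. The log2 ratios of Alb and Calr were -0.19 and -0.17, and 2904 genes were lower by 2-fold.

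Median-of-ratios scaling moved the median of all measured genes from -0.23 to 0.0058. It gave -0.26 for fatty acid oxidation, -0.23 for G1/S targets and 0.027 for complement and coagulation, with 0.19 for Hp and 1031 genes lower by 2-fold. CPM without mitochondrial and ribosomal protein genes and the top 20 genes gave 0.019 for Hp. With no filter and 1 UMI added, 4860 genes were lower by 2-fold and the dendritic median was 2.48, and from 50 CPM and 100 UMIs 399 genes were higher and 555 lower. These last numbers follow in part from how many genes pass the filter.

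In barcodes with at least 0.05% Malat1 the medians were 0.14 for complement and coagulation and 2.48 for dendritic markers, and the macroscopic share with G1/S genes was 92.3%. Without the leading genes of clusters 7 and 13 all 9 lists that hold one kept their sign and stayed within their interval. Among them, acute-phase genes had -0.37, oncofetal genes 0.68 and the female-biased list -2.98. The shared clusters hold other cell types, so values relative to them also carry the ratios of those cells. Relative to the shared clusters the medians became -0.93 for secreted proteins, -1.17 for G1/S targets, -1.28 for G2/M genes, -1.24 for the RB and E2F network, 0.24 for NRF2 targets, 1.45 for dissociation stress, 1.32 for macrophage markers and 4.66 for dendritic markers. Gene ratios whose interval excluded 0 changed sign there to -1.44 for Hist1h2ap, -0.86 for Alb, -1.24 for Cdkn1a, 0.13 for Gstm1, 0.19 for Mgst1, -0.64 for Fabp1, -1.37 for Birc5, -0.27 for Jund and 1.32 for C1qa. Notch1 and Notch2, whose intervals included 0, turned to 0.20 and -0.75.

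Shares of classes moved with the filters on barcodes. With at least 2000 UMIs and 500 genes the early shares were 2.67% hepatocyte-like, 56.5% macrophage-like and 6.67% cholangiocyte-like, and the neutrophil-like share was 0% in both libraries. With a mitochondrial share of at most 10% the early shares were 60.9% macrophage-like and 6.44% cholangiocyte-like, the B cell-like and plasmacytoid-like shares were 0% in both libraries, and the dendritic median was 2.57. With no limit on the mitochondrial share the early macrophage-like share was 66.2%, plasmacytoid-like cells were 0% in both libraries, unnamed cells were 19.3% and 10.8%, and the dendritic median was 2.60. With at least 500 UMIs and 200 genes B cell-like and plasmacytoid-like cells were 0% in both libraries and unnamed macroscopic cells 14.3%. With called doublets kept plasmacytoid-like cells were 0% in both libraries and unnamed early cells 21.3%. Leiden resolution 1.0 gave 1.34% plasmacytoid-like and 21.4% unnamed early cells. The macroscopic library held 1 cholangiocyte-like cell under all these settings except Leiden resolution 1.0, and 0 in the reported one. A class at 0% had no cluster that met the naming rule, and this does not show that its cells were absent.

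Shares of hepatocyte-like cells with at least 3 UMIs of a list depend on the depth and the minimum by construction and do not measure cycling. For G2/M genes the early and macroscopic shares were 56.5% and 62.9% when thinned to 1000 UMIs, 97.8% and 98.2% at 4000 UMIs, and 100% and 99.2% when not thinned. For G1/S genes they were 73.9% and 60.5% at 1000 UMIs and 100% and 97.6% when not thinned, and the macroscopic share was 98.2% at 4000 UMIs. With at least 2 UMIs the early G2/M share was 91.3% and the G1/S shares 100% and 96.6%. With at least 5 UMIs the shares were 63.0% and 71.8% for G2/M and 80.4% and 74.4% for G1/S. The macroscopic G2/M share was 84.7% with at least 500 UMIs and 200 genes, with at least 2000 UMIs and 500 genes and with called doublets kept, which lies inside the range of 82.9% to 94.9% over repeated thinning. With no limit on the mitochondrial share it was 80.3%, and the macroscopic G1/S share 75.9%.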

Other observations

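The tests of lesion stage, of a general difference in hepatocyte genes and of sex were chosen after their results had been seen, and the patterns themselves were found in these data, as was the idea of overlapping genes (from names such as Nme2). The tests of nuclear RNA, free RNA, overlapping genes and depth were written down before their values were seen.

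The first pattern is the set of 83 macroscopic hepatocyte-like barcodes with almost no Malat1. Other RNAs kept in the nucleus (7 of 10 listed were found) stood at 0.0695 of their level in the other hepatocyte-like barcodes (0.0484 to 0.0968), a value that pieces of cytoplasm without a nucleus could give. Mitochondrially encoded RNA was low as well, at 0.0587 of that level (0.0574 to 0.0600), which a loss of nuclei alone does not account for. Markers of other classes stood at 0.0916 of their level over all barcodes (0.0851 to 0.0985). This lay under the 0.25 set in advance for excluding RNA free in the suspension. However, the 83 barcodes were grouped by their hepatocyte profile, and the reference includes cells that express those markers. The test therefore cannot decide, and free RNA stays open. The share of such barcodes, 66.9% against 0 of 46, cannot be told apart between a state of the cells at the macroscopic stage and a difference between preparations, because each stage has 1 library.

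The second pattern is a set of 63 genes at least 2-fold higher in the macroscopic library in hepatocyte-like cells and in each of the 3 shared clusters, where 6 genes were lower. Of these genes 18 (28.6%) overlap another gene on the same strand, against a median of 4.76% in matched random sets (1.59 to 11.1), so a difference in how reads of overlapping genes were counted may explain part of the set. In cells thinned to 2000 UMIs the median log2 ratio over the shared clusters was 1.73 (1.48 to 2.04), against 1.87 at full depth, and so stayed above 2-fold. The low end lay under the 1.498 set in advance for excluding depth, and random thinning leaves the expected CPM of a cell unchanged, so depth stays open. Lesion stage cannot be told apart from a difference between preparations for these 63 genes.

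The third pattern is the lower level of female-biased liver genes, with a median log2 ratio of -3.24 (-5.06 to -1.56). Its interval overlapped narrowly that of the cytochrome P450 list (-1.62 to -0.73), whose median was -1.10. Overlap of intervals does not test the difference between the medians. Whether the fall goes beyond a general difference in hepatocyte genes is therefore not decided. The male-biased list, at 0.41 (-3.88 to 2.42), had members in both directions and decides nothing about the sex of the animals. Stage and sex differ between the same libraries, so both stay open.

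Other values stood out and were chosen after seeing the data, without a test. Cholangiocyte-like cells held 91.5 Ttr UMIs per 100 Alb UMIs (87.7 to 95.5), against 34.3 in cluster 7, but 0.244 Apoa1 UMIs against 28.7. The unnamed cluster 2, with 187 early cells, held 24.7 Rgn UMIs per 100 Alb UMIs against 0.0194 in cluster 7, and against 7.79, 16.2 and 5.82 in the macrophage-like clusters 0, 1 and 3. Rgn is a leading gene of cluster 2. Its leading genes Pck1, Hpd, Agxt and Mat1a were also above those 3 clusters by this measure. Oat, another leading gene, was not, at 39.6 against 40.5, 56.6 and 58.7. Cluster 3, led by Fabp7, Marco and Ifi27l2a, held 37.4% of cells with G2/M genes after thinning. In hepatocyte-like cells Cd74 had 1023 CPM in the macroscopic library while Gpnmb had 0.360 CPM, against 23464 and 176 CPM in the macroscopic cells of cluster 6.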
